A study of Arabidopsis thaliana with 8 samples.

How the data were processed

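Gene expression in seedlings of Arabidopsis thaliana, accession Ws-0, was measured on Affymetrix ATH1 arrays, 1 array per sample. The 8 arrays fall into 4 groups of 2 biological replicates: a 35S:LEC2-GR line without treatment, the same line after 1 h and after 4 h with dexamethasone, and non-transgenic seedlings after 4 h with dexamethasone. The line makes a fusion of the transcription factor LEAFY COTYLEDON2 (LEC2) with the hormone-binding part of the glucocorticoid receptor, which keeps the fusion inactive until dexamethasone is added. Biotin-labelled target was made from polyA RNA, per the labels' protocols.

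The authors' deposited table holds 1 intensity per probe set and array on a linear scale, made with MAS5 according to the submitters' processing notes, which give no version. The values show that every array had been scaled: the mean after 2% of the values were trimmed from each end was 500.05 on all 8 arrays. The table gives no detection calls. Of 22810 probe sets, 64 are controls and were left out of the tests. Each array also came with a record of the instrument run. The records give the same scan day and the same array lot for all 8 arrays, and the order of the scans, the fluidics position and which fields are filled put wild type and the uninduced line in a first fluidics run and the 1 h and 4 h samples in a second; the runs are inferred, not stated. The position of 4 h replicate 2 is blank, and it was scanned 25 minutes after the array before it, against 11 or 12 minutes for the others, also between both runs, so its place in the second run is the least sure. Such a run lies between the groups compared for 4 h or 1 h against the uninduced line and for 4 h against wild type, which by themselves do not separate run from group, while 4 h against 1 h and wild type against the uninduced line lie within a run. The record of 4 h replicate 2 carries a comment on high background on part of the image.

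Probe sets were named only from the platform annotation supplied with the table. Of the 22746 probe sets that are not controls, 13513 (59.4%) list a single gene, 503 list several and 8730 are not listed, which leaves them unnamed here. Of those with a single gene, 13436 were matched to the RefSeq gene table of assembly TAIR10.1, used for names only, and 77 were not. No probe set carries the name of LEC2 itself, so the transgene's transcript was not read out and the labels could not be checked against it.

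Values were turned into log2(intensity + 45), where 45 is the 25th percentile of the table. A probe set was tested when it lay above its own array's 40th percentile on at least 2 of the 8 arrays, which left 15026. Fold changes are on this log2(value + pseudocount) scale and understate the change of genes with low signal. All 8 arrays were fitted together with 1 mean per group in limma 3.58.1 under R 4.3.3 (lmFit, eBayes with a mean-variance trend), with 4 residual and 11.2 prior degrees of freedom. A probe set was called when its Benjamini-Hochberg adjusted p within a comparison was under 0.05. The comparisons were 4 h against uninduced, 1 h against uninduced, 4 h against wild type at 4 h, 4 h against 1 h, and wild type at 4 h against uninduced; a probe set was counted as changed against both controls when it was called in the same direction in the first and the third. The last comparison differs in dexamethasone, time and transgene together, since the series has no untreated wild type. The number of arrays, 2 per group, limits the precision of every value.

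Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, again with an estimated correlation, and with fry; a list needed at least 3 tested loci. Before the data were examined, 20 lists were fixed: seed storage proteins, oil body proteins, fatty acid and triacylglycerol synthesis, late embryogenesis abundant (LEA) proteins, storage protein processing proteases, embryo and seed maturation transcription factors, repressors of the embryonic programme, early auxin response, auxin biosynthesis, gibberellin metabolism, abscisic acid and cold response, photosynthesis, circadian clock, touch and wounding, heat shock, pathogen defence, flavonoid pathway, root markers, cell division and reference genes. Few of their genes have a probe set of their own in the annotation, so further lists were written once that coverage was known and before any group value had been computed, among them photosystem and electron transport subunits, cytosolic ribosomal proteins, small heat shock proteins and chaperones, other seed maturation genes, root-enriched genes, and the CML, expansin and XTH, SWEET, UGT and GST families and mitochondrially encoded subunits. The SWEET list was matched by symbol and holds SWEETIE, which is not a sugar transporter of that family. The photosystem and electron transport list, called photosystem genes for short, also holds Calvin cycle genes, PRK and SBPASE among them. A list of 30 sugar starvation genes was written after the leading decreases had been seen.

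The genes named were fixed by a rule set before the data were examined: per comparison, the 8 largest increases and the 6 largest decreases among called probe sets of a single gene whose arrays did not overlap between the groups, and up to 4 members with the smallest p from each list described. The tested members of the sugar starvation list and members that changed sign under another scaling are named besides. Genes chosen after their values were seen are said to be so. The fitting step was tested on simulated data with 100 probe sets changed by a log2 of 1 and 100 by a log2 of 2 in the 4 h group: for 4 h against uninduced it recovered 74% and 100% of them with 10 false calls among 15026, and it made 0 calls between the unchanged groups. Alternatives tried were pseudocounts of 1 and of 180, no filter, a filter at the 60th percentile, quantile normalization, a common trimmed mean, no mean-variance trend, a fit of only the groups compared, the replicate number as a block, and each array left out in turn. Plots were drawn with matplotlib.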

Results

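The seedlings were 8 days old, and each of the 4 groups had 2 arrays. Replicates correlated at 0.969 to 0.980 across probe sets on the log2 scale, and the median absolute difference between replicates was 0.17 to 0.22. The ratio of the 3′ to the 5′ GAPDH control, a sign of RNA integrity, ran from 1.59 in 4 h replicate 2 to 3.37 in 1 h replicate 1. The same ratio for actin ran from 6.90 in uninduced replicate 1 to 13.4 in uninduced replicate 2. The array medians lay between 170 and 191. The highest value on an array was 55404 and 70130 in the uninduced line and 36445 to 48607 on the other 6 arrays.

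The comparison of 4 h transgenic with wild type seedlings, both with dexamethasone, asks what the LEC2 fusion adds to the treatment. Of the 8 leading increases, AT3G54940 and OLEO3 came from the seed gene lists. The papain-type cysteine protease AT3G54940 had a signal of 3311 ± 676 (SD, n = 2) at 4 h, 12 ± 5.23 in wild type and 53.7 ± 5.94 in the uninduced line. OLEO3, an oleosin of the oil bodies of seeds, stood at 2635 ± 16.9 at 4 h, 60.4 ± 28.2 in wild type and 196 ± 80.5 in the uninduced line. Against wild type AT3G54940 rose by 5.87 (SE 0.27, adjusted p = 1.7e-09) and OLEO3 by 4.70 (SE 0.24, adjusted p = 5.3e-09) on the log2 scale, and against the uninduced line they rose by 5.07 and 3.52.

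The other leading increases against wild type were AT1G04660, a glycine-rich protein (5.56), AT2G34700 of the Ole e 1 family (4.63), AT5G02230, a haloacid dehalogenase-like hydrolase (4.58), the GDSL-type lipase AT5G08460 (4.34), AT3G43270 of the pectin methylesterases (4.23) and AT5G57785 (3.77). Their SE ran from 0.14 to 0.29. AT1G04660 was already at 1322 ± 505 in the uninduced line against 42.2 ± 39.4 in wild type. The largest decreases were smaller. AT4G11190, a dirigent-like protein, fell by 2.32, AT5G02540 fell by 2.29, AT4G22610 fell by 2.01, AT1G73600, a phosphoethanolamine methyltransferase, fell by 1.96 and AT3G26450 fell by 1.85. AT5G28520 fell by 2.25 (adjusted p = 0.0035), a call that ended without wild type replicate 1 (adjusted p = 0.139).

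The list of other seed maturation genes had 17 loci with a probe set of their own, of which 3 passed the filter. High values on the 2 arrays of 1 group satisfy the filter, so genes high only at 4 h can enter the list. With no filter the list's mean log2 change against wild type was 0.547, against 2.92 with it. Of the 3 tested members 2 rose against wild type, and 3 when adjusted over the list alone. The camera adjusted p was 1.9e-05, 0.574 with an estimated correlation and 0.0776 with no filter. The risen members were not picked at random from the 17. The 2 were AT3G54940 and AT1G65090, the latter from 22.9 in wild type to 224 at 4 h (log2 1.99). The call of AT1G65090 ended without any of the 4 arrays compared or with a pseudocount of 1 (limma adjusted p = 0.269). PDF2.1, a defensin, differed by 0.92 from wild type and did not pass the test. A named probe set was present for 5 seed storage, 4 oil body and 13 LEA genes, of which only 1, 1 and 2 passed the filter. Since high values on both 4 h arrays would have sufficed, the rest of these genes did not reach the filter's level on both. Most of the named genes of these lists were therefore not seen to rise to that level at 4 h. A smaller rise was not tested. The cupin AT4G36700 rose from 7 ± 0.849 in wild type to 260 ± 30.7 at 4 h, and the LEA protein M10 from 8.65 ± 4.60 to 447 ± 34.3. Both started near the bottom of the scale, and with a pseudocount of 1 their adjusted p against wild type was 0.208 for AT4G36700 and 0.160 for M10; AT4G36700 also lost its call without 4 h replicate 2 (adjusted p = 0.0615). LEA18 rose by 1.25 (adjusted p = 0.0292), a call lost without any of the 4 arrays (adjusted p = 0.117 to 0.196).

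**Figure D1:**
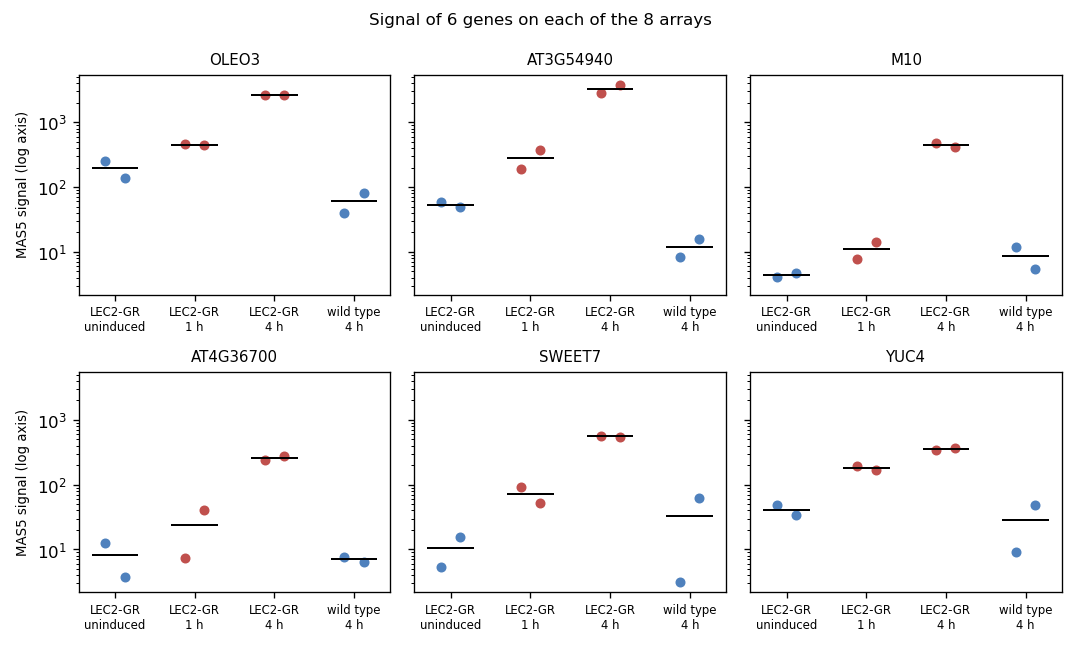
Signal (MAS5 intensity, log axis) of 6 genes on each of the 8 arrays, red for the line with dexamethasone and blue for the controls, with bars at the group means (n = 2). OLEO3 went from 60.4 in wild type to 2635 in the line at 4 h, and M10 from 8.65 to 447.

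Auxin genes differed between the line and wild type. YUC2 and YUC4, flavin monooxygenases of auxin synthesis, rose by 1.72 (SE 0.19, adjusted p = 2.6e-05) and 2.50 (SE 0.33, adjusted p = 1.4e-04), while YUC6 fell by 1.40 (adjusted p = 0.0288; 0.11 to 0.242 without any of the 4 arrays). The list of auxin biosynthesis, with 2 of 3 tested members up and 1 down, did not pass (adjusted p = 0.0586; adjusted p = 0.590 with an estimated correlation), and the counts adjusted over the list alone were the same. Of 5 tested early auxin response genes 3 rose and 1 fell, also when adjusted over the list alone (list adjusted p = 0.342). IAA29, a repressor of auxin response, fell by 1.48 (adjusted p = 0.0013) and IAA30 rose by 1.55, a call that ended without either 4 h array or without wild type replicate 1 (adjusted p = 0.0637 to 0.239). GH3.3 and WES1 encode auxin-conjugating enzymes. At 4 h WES1 was called lower than in the uninduced line, a call lost without uninduced replicate 1 or either 4 h array. Against wild type GH3.3 rose by 0.78 and WES1 by 0.66. GH3.3 lost its call without 4 h replicate 1 or 2 or wild type replicate 2 (adjusted p = 0.0734 to 0.235), and WES1 without any of the 4 arrays (0.0721 to 0.346).

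Sugar transporters of the SWEET family split. SWEET7 rose by 3.08 (SE 0.40, adjusted p = 1.3e-04), from 32.8 ± 42.0 in wild type to 562 ± 15.3, while SWEET1, SWEET2 and SWEET17 fell by 1.08, 1.12 and 1.48. In all, 1 of 8 tested members rose and 4 fell, and 1 and 5 when adjusted over the list alone (list adjusted p = 0.0586). Without wild type replicate 1 the adjusted p of SWEET1 was 0.0719.

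In all, 996 of 15026 probe sets differed between the line and wild type at 4 h, 514 higher and 482 lower, of which 315 rose and 215 fell by at least 2-fold. Of the 996, 458 carry a single gene name. The count was 593 without 4 h replicate 2, the array with the comment on its background, 640 without 4 h replicate 1, 530 without wild type replicate 1 and 494 without wild type replicate 2.

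Both controls together narrow the list to 653 probe sets called in the same direction at 4 h, 355 higher and 298 lower, of which 290 carry a single gene name. AT3G54940, AT2G34700, AT5G02230, AT5G08460, OLEO3, AT3G43270, M10, SWEET7, YUC2, YUC4 and AT4G36700 were among the higher ones. IAA29, SWEET1 and SWEET2 were among the lower ones, though SWEET1 lost its call against the uninduced line without uninduced replicate 1 (adjusted p = 0.0925) or 4 h replicate 1 (0.0952). IAA29 went from 646 ± 57.1 in the uninduced line and 279 ± 19.3 in wild type to 74.1 ± 36.0 at 4 h. Of the 355 higher probe sets, 217 were also called higher at 1 h, and 140 were higher at 4 h than at 1 h. Of the 298 lower ones, 134 were already lower at 1 h and 194 were lower at 4 h than at 1 h. The median change of the 355 was 0.95 at 1 h, 1.41 at 4 h and 0.04 in wild type against the uninduced line. For the 298 these medians were -0.52, -1.20 and -0.24, and 99 of the 298 were also called lower in wild type.

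These overlaps rest on shared 4 h arrays. With no effect at all, 100 simulations on shared arrays gave a mean of 0.05 and at most 1 such probe set, and independent lists of the same sizes would share 96.7 higher and 81.1 lower ones. A further 82 probe sets were called in opposite directions. The covariance of the changes was 0.172 against 0.029 in the simulations, and the correlation 0.46 against 0.50. Because they held no change, the simulations do not show what shared arrays add when both comparisons hold changes. This also limits them for the overlaps of 1 h and of wild type given below. The shared group was not split, since each part would be a lone array, so part of the excess may come from those arrays. The count was 405 without 4 h replicate 2, 385 without wild type replicate 1 and 355 without wild type replicate 2.

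**Figure D2:**
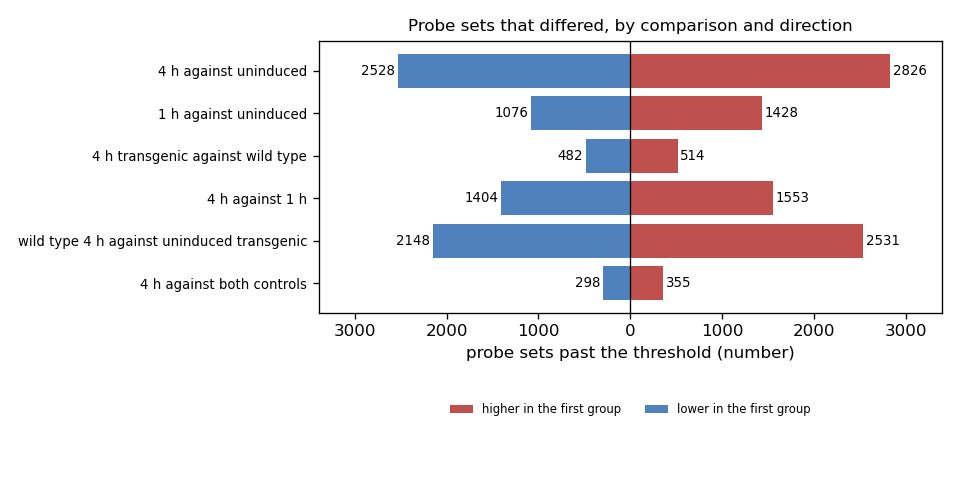
Number of probe sets past the threshold in each comparison, higher (red, to the right) and lower (blue, to the left) in the group named first. The 4 h line differed from the uninduced line at 5354 probe sets and from wild type at 996.

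Against the uninduced line, 4 h of dexamethasone asks for the effect of induction together with that of treatment and time. The change was broad. AT5G62360, of the invertase and pectin methylesterase inhibitor family, rose from 153 ± 14.8 to 6843 ± 1162 (log2 5.11, SE 0.18, adjusted p = 1.9e-10). After it and AT3G54940 came AT2G34700 (4.65), AT2G41730 (3.96, on a probe set that can cross-hybridise), AT5G48430 (3.85), AT5G02230 (3.80), AT4G30650 of the low temperature and salt responsive family (3.75) and AT5G08460 (3.71). AT1G33055 fell by 5.08, from 1681 ± 304 to 5.60 ± 2.40, and AT4G27450, an aluminium-induced-like protein, by 4.84, from 9174 ± 1641 to 286 ± 128. AT2G32150 fell by 4.46, MCCA, a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, fell from 4542 to 209, AT2G20670 fell by 4.08 and the F-box Kelch protein AT1G23390 fell by 3.69.

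Small heat shock proteins and chaperones rose: 5 of 7 tested members were higher at 4 h than in the uninduced line, and 5 when adjusted over the list alone (adjusted p = 1.3e-04; adjusted p = 0.423 with an estimated correlation). AT2G29500 rose by 2.98, AT1G54050 by 2.84, AT5G51440 by 2.77 and the Hsp70 AT3G09440 by 2.62. All 3 tested seed maturation genes of the added list rose, AT3G54940, PDF2.1 (2.73) and AT1G65090 (1.76), and likewise over the list alone (adjusted p = 0.0054; adjusted p = 0.423 with an estimated correlation and 0.546 with no filter). AT1G65090 lost its call without uninduced replicate 1 or either 4 h array (adjusted p = 0.052 to 0.0722), and with a pseudocount of 1 (adjusted p = 0.122). Of 28 cytosolic ribosomal protein genes 10 rose and 0 fell, 11 and 0 over the list alone (adjusted p = 0.0097; adjusted p = 0.4995 with an estimated correlation), led by AT2G20450 (1.00), AT1G15250 (0.91) and AT2G32060 (0.89). AT1G15250 had an adjusted p of 0.0523 without 4 h replicate 1. With quantile normalization 19 of the 28 ribosomal genes rose, among them AT1G52300 and AT2G34480, whose changes had the other sign and were not called before. All 3 abscisic acid and cold genes rose, COR15A by 3.48, while their list did not pass (adjusted p = 0.0610). COR15B lost its call without uninduced replicate 2 (adjusted p = 0.215) or 4 h replicate 2 (0.155) and with no filter (0.0793), and COR47 without uninduced replicate 1 (0.123) or 4 h replicate 2 (0.0501).

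Photosynthesis genes fell. All 8 tested photosystem and electron transport genes were lower at 4 h, also over the list alone (adjusted p = 1.3e-04; adjusted p = 0.423 with an estimated correlation), and so were the 3 of the photosynthesis list, which the longer list also holds (adjusted p = 0.0097; adjusted p = 0.423 with an estimated correlation). LHCB4.2, a chlorophyll-binding antenna protein, fell from 28584 ± 1310 to 10106 ± 111, PRK, the phosphoribulokinase of the Calvin cycle, fell by 0.97, SBPASE fell by 0.71 and RCA fell by 0.65. These genes lie at the bright end of the scale, where the uninduced arrays reached the highest values. With quantile normalization 5 of the 8 and 1 of the 3 fell, PSAE-1 changed sign, RCA had an adjusted p of 0.156, and the photosynthesis list had an adjusted p of 0.203.

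In this comparison 5354 probe sets were called, 2826 higher and 2528 lower, of which 1310 rose and 965 fell by at least 2-fold. A single gene name belongs to 2723. Without 4 h replicate 2 the count was 3962.

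Much of this was also seen in wild type. Wild type at 4 h against the uninduced line sets the 2 control groups side by side and mixes dexamethasone, time and transgene. AT4G30650 rose from 206 ± 62.1 to 6617 ± 765 (log2 4.75, SE 0.26, adjusted p = 5.0e-09), followed by AT5G62360 (4.61), the transporter AT4G34950 (4.38), COR15A, a cold-induced chloroplast protein (4.27), AT2G41730 (3.80), AT5G05600, a 2-oxoglutarate-dependent oxygenase (3.54), AT5G48430 (3.44) and AT5G35735 (3.44). AT1G33055 fell by 4.85, AT4G27450 fell by 4.64, MCCA fell by 4.22, AT4G10910 fell by 4.00, AT1G04660 fell by 4.00 and AT2G32150 fell by 3.98. The fall of AT1G04660 was not shared by the line at 4 h, where its signal was 3912 ± 902 against 1322 ± 505 uninduced.

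The small heat shock, ribosomal, photosystem and photosynthesis lists were called in wild type too, while the other seed maturation genes were not (adjusted p = 0.947). Of the small heat shock proteins and chaperones 5 of 7 rose (adjusted p = 1.2e-04; adjusted p = 0.390 with an estimated correlation), and all 3 abscisic acid and cold genes did (adjusted p = 0.0223; adjusted p = 0.539 with an estimated correlation), COR15A, COR15B (2.13) and COR47 (0.54). Over the list alone the counts were 5 and 3. COR47 lost its call without uninduced replicate 1 or either wild type array (adjusted p = 0.0501 to 0.189). Of 28 cytosolic ribosomal protein genes 8 rose, 7 over the list alone (adjusted p = 0.0379; adjusted p = 0.663 with an estimated correlation), and this list's adjusted p was 0.0524 without uninduced replicate 1, 0.0806 without uninduced replicate 2 and 0.296 without wild type replicate 2. All 8 photosystem genes fell (adjusted p = 1.2e-04; adjusted p = 0.401 with an estimated correlation), as did the 3 photosynthesis genes (adjusted p = 0.0157; adjusted p = 0.390 with an estimated correlation), both also over the list alone. LHCB4.1 fell by 0.42, a call lost without uninduced replicate 1 or either wild type array (adjusted p = 0.0508 to 0.117), and stood at 0.11 with quantile normalization. There PSAE-1 changed sign too, 4 of the 8 photosystem and 1 of the 3 photosynthesis genes fell (list adjusted p = 0.0264 and 0.331), and 12 of the 28 ribosomal genes rose. Of 4 proteases that process storage proteins 3 fell, also over the list alone, namely GAMMA-VPE by 1.14, AT1G62290 by 0.75 and the aspartic protease APA1 by 0.68 (adjusted p = 0.0245; adjusted p = 0.390 with an estimated correlation; 0.0544 without uninduced replicate 2).

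Wild type and uninduced line differed at 4679 probe sets, 2531 higher and 2148 lower in wild type. The count was 2946 without wild type replicate 1. The 4 h line and wild type shared 1992 higher and 1676 lower calls against the uninduced line and had 54 in opposite directions, where independent lists would share 476 and 361 and the simulations at most 1. The covariance was 0.453 against 0.029 simulated. None of these stress and photosynthesis lists was called between the line and wild type at 4 h: small heat shock proteins had 0 of 7 members called (limma; list adjusted p = 0.342), abscisic acid and cold genes 0 of 3 (0.359), cytosolic ribosomal proteins 0 of 28 (0.342), photosystem genes 0 of 8 (0.359) and photosynthesis 0 of 3 (0.633). Of the storage protein proteases 1 of 4 rose there, AT1G62290 (0.69; list adjusted p = 0.359), which lost its call without any of the 4 arrays (adjusted p = 0.0523 to 0.204).

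**Figure D3:**
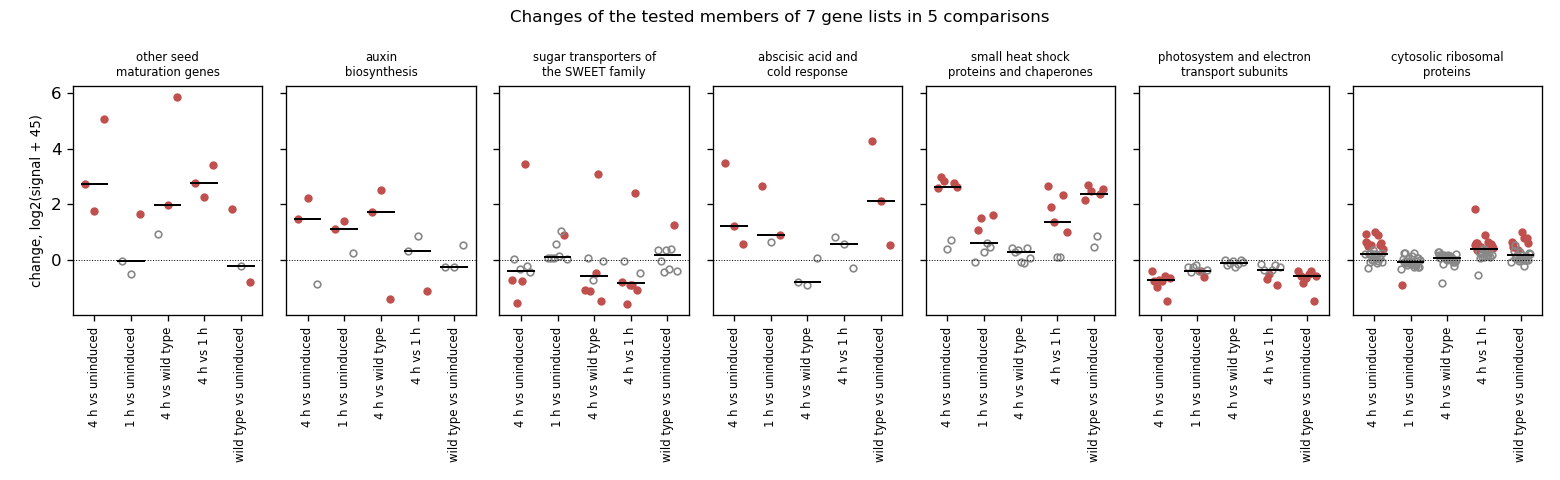
Change of every tested member of 7 gene lists in the 5 comparisons, in log2(signal + 45), with filled red points for members that passed the test and bars at the list medians. The list of photosystem genes, which also holds Calvin cycle genes, had a median of -0.73 for 4 h against uninduced. Its median was -0.59 for wild type against uninduced and -0.10 for 4 h against wild type. With quantile normalization LHCB4.1 changes sign in wild type against uninduced, and PSAE-1 there and in 4 h against uninduced. AT1G52300 and AT2G34480 change sign in 4 h against uninduced.

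The 1 h comparison asks which transcripts had moved soon after induction. With no wild type at 1 h, it does not separate induction from dexamethasone, time and handling. AT5G62360 was already at 7660 ± 2196 against 153 ± 14.8 in the uninduced line (log2 5.25, SE 0.18, adjusted p = 9.6e-11). AT5G05600 (4.26) and AT2G38240 (3.75), both 2-oxoglutarate-dependent oxygenases, AT5G02230 (3.76), the dehydrin LTI30 (3.71), the VQ motif protein AT2G22880 (3.70), AT5G35735 (3.44) and AT2G39980 (3.27) followed. AT2G20670 fell by 4.72, AT1G33055 fell by 4.71, AT1G50040 fell by 3.64, AT4G10910 fell by 3.58, AT1G23390 fell by 3.52 and the expansin EXPA8 fell by 3.18.

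Of the genes that marked the line at 4 h, AT5G02230 had reached 7598 at 1 h against 7819 at 4 h. YUC2 (1.12), YUC4 (1.38) and OLEO3 (1.08) also rose at 1 h, though YUC4 had an adjusted p of 0.053 without 1 h replicate 1 and OLEO3 of 0.0681 without uninduced replicate 2. The auxin biosynthesis list, with 2 of 3 up, did not pass (adjusted p = 0.0901). M10 and AT4G36700 had changes of 0.18 and 0.33 that did not pass. The small heat shock proteins, 3 of 7 up (adjusted p = 0.0383; adjusted p = 0.504 with an estimated correlation), the abscisic acid and cold genes, 2 of 3 up (adjusted p = 0.0383; 0.504 with an estimated correlation), the photosynthesis genes, 2 of 3 down (adjusted p = 0.0388; adjusted p = 0.504 with an estimated correlation), and the photosystem genes, 2 of 8 down (adjusted p = 0.0131; adjusted p = 0.504 with an estimated correlation), passed at 1 h. Over the list alone the counts were 3, 2, 3 and 5. Each of these 4 lists lost its call without uninduced replicate 2 and without either the first or the second 1 h array (adjusted p = 0.0633 to 0.169), and both photosynthesis lists and the heat shock list lost it with quantile normalization (adjusted p = 0.0624 to 0.630). With a pseudocount of 180 the abscisic acid, photosynthesis and heat shock lists lost it (adjusted p = 0.0789 to 0.0828), and with fry the abscisic acid, photosystem and heat shock lists did (adjusted p = 0.0634 to 0.105).

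At 1 h 2504 probe sets were called, 1428 higher and 1076 lower. The count was 1735 without uninduced replicate 1, 2021 without uninduced replicate 2, 1897 without 1 h replicate 1 and 2189 without 1 h replicate 2. Without 4 h replicate 2, which is not compared here but enters the fit, it was 2428. With 4 h they shared 986 higher and 908 lower calls against the same uninduced arrays, and 21 went in opposite directions. Independent lists would share 269 and 181, and the covariance was 0.347 against 0.029 simulated. The overlap with wild type at 4 h, which rests on the same uninduced arrays, was 811 higher, 821 lower and 51 opposite, where independent lists would share 240.5 and 153.8, the simulations gave at most 1 and the covariance was 0.279 against 0.029 simulated.

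The direct comparison of 4 h with 1 h tests whether the transcripts moved further or turned back. AT2G41730 rose by 4.60 (SE 0.35, adjusted p = 8.2e-07), from 84.6 ± 93.7 to 2680 ± 537, and AT2G34700 by 4.22, from 126 ± 11.4 to 3141 ± 130. AT3G54940 (3.41), M10 (3.14), the glucosyltransferase UGT73C1 (2.90), PDF2.1 (2.76), the small heat shock protein AT1G53540 (2.66) and AT5G08460 (2.55) followed. AT1G15010 fell by 3.17, AT4G27450 fell by 2.42, AT1G15640 fell by 2.16, and AT1G65490, AT4G38690 and AT5G11070 each fell by 2.13. M10 had an adjusted p of 0.0982 with a pseudocount of 1.

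Cytosolic ribosomal proteins rose between 1 h and 4 h in 14 of 28 genes, 17 over the list alone, and fell in 0 (adjusted p = 5.3e-07; adjusted p = 0.326 with an estimated correlation). AT1G15250 rose by 1.83 after a fall at 1 h. The 3 seed maturation genes all rose, also over the list alone (adjusted p = 1.4e-04; adjusted p = 0.326 with an estimated correlation and 0.233 with no filter). Of the small heat shock proteins 5 of 7 rose, 5 over the list alone (adjusted p = 1.4e-04; adjusted p = 0.326 with an estimated correlation). Of the photosystem genes 3 of 8 fell, 3 over the list alone (adjusted p = 0.0022; adjusted p = 0.503 with an estimated correlation), LHCB4.2 by 0.89, PRK by 0.69 and SBPASE by 0.51, and this list had an adjusted p of 0.0552 without 1 h replicate 1. SBPASE lost its call without that array (adjusted p = 0.0741) and without 4 h replicate 2 (0.0849). In the SWEET family 5 of 8 fell and SWEET7 rose by 2.41, with the same counts over the list alone (adjusted p = 0.0175; adjusted p = 0.503 with an estimated correlation; 0.0949 without 1 h replicate 1, 0.0612 with no filter and 0.0769 with the filter at the 60th percentile). SWEET7 lost its call with a pseudocount of 1 (adjusted p = 0.0984).

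Between 4 h and 1 h 2957 probe sets were called, 1553 higher and 1404 lower at 4 h. The count was 1839 without 4 h replicate 2, 1846 without 4 h replicate 1 and 1846 without 1 h replicate 1. Both groups lie in the same inferred fluidics run. By contrast, 4 h and 1 h against uninduced and 4 h against wild type each cross from one run to the other and by themselves do not separate run from group. Within a run, 334 of the 653 probe sets changed against both controls also differed between 4 h and 1 h in the same direction. Wild type against uninduced, also within a run, shared 1992 higher and 1676 lower calls with 4 h against uninduced. The latter comparison crosses the runs, and both rest on the same uninduced arrays.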

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

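The induced line changed differently at 4 h and at 1 h: the direct test between both times called 2957 probe sets. The series has no wild type at 1 h. The difference between both times therefore does not separate induction from the length of dexamethasone treatment, time of harvest and handling. The list of cytosolic ribosomal proteins had an adjusted p of 5.27e-07 for that difference, with AT2G20450 up by 0.88 and AT2G32060 up by 0.65. The added list of seed maturation genes had 0.000136, with AT3G54940 up by 3.41. The small heat shock proteins and chaperones had 0.000136, with AT5G51440 up by 2.33. The photosystem subunits had 0.00224 and the SWEET sugar transporters 0.0175, with SWEET2 down at -1.61. None of these 5 lists passed with an estimated correlation. The ribosomal, small heat shock and photosystem lists were also called in wild type against uninduced. Between the line and wild type at 4 h they had 0 of 28, 0 of 7 and 0 of 8 members called.

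Of the 2957, 21 were called against the uninduced line in opposite directions at 1 h and at 4 h. Among them, 17 were higher at 1 h and lower at 4 h, and 4 were the reverse. AT1G65490 stood at 1.48 at 1 h and at -0.66 at 4 h, though the latter call was lost without uninduced replicate 1 (adjusted p = 0.174) or 4 h replicate 2 (adjusted p = 0.176). AT1G15250, a ribosomal protein gene, stood at -0.92 and 0.91, and lost its 4 h call without 4 h replicate 1 (adjusted p = 0.0523) and its 1 h call without uninduced replicate 1 (0.0722) or 1 h replicate 1 (0.099). AT2G45820 stood at 0.78 and -0.74.

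The probe sets changed at 4 h against both controls could in part reflect the inferred fluidics run, since both controls were in the first run and the 4 h arrays in the second. Of them, 51.1% (334) also differed between 4 h and 1 h in the same direction. A run effect alone does not account for these, because those groups share a run. In 100 simulations with 1 h and 4 h equal, at most 0.249% did so. A run shift added to a change with time could also give such calls. The simulations cannot exclude that, since they held no change from 1 h to 4 h. The place of 4 h replicate 2 in the run is the least sure. For the other 319 the run cannot be told apart from an effect of induction, since no group lies in both runs; 15 of the higher and 4 of the lower ones differed between 4 h and 1 h in the opposite direction, and 52 and 36 were called neither at 1 h nor between both times. The array with a comment on its background does not account for the set either: 57.6% of the probe sets were still called without it, against both controls and in the same direction. An effect of the induced fusion stays an untested hypothesis for the first part and open for the second.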

How the results depend on the processing

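All settings here were planned before the data were examined. The setting with the array batch as a block was not run, because all arrays share a scan day, and rescaling to a common trimmed mean moved nothing, because the arrays had been scaled that way. Pseudocounts, filters, quantile normalization, the variance model and the fit of only the groups compared left every count of called probe sets within 1.5 times its main value. The list tests were not run with the other variance model or the fit of only the groups compared. Under the rest of these settings the number of list calls stayed within the same limit. Leaving out an array gave 3962 to 5568 calls for 4 h against uninduced, 1735 to 2428 for 1 h against uninduced, 494 to 1118 for 4 h against wild type (main 996), 1839 to 3021 for 4 h against 1 h (main 2957), 2946 to 4897 for wild type against uninduced (main 4679), 355 to 718 against both controls (main 653) and 15 to 24 list calls (main 21). The lower ends leave a group with a lone array, which is assumed to vary like the others. The list calls numbered 0 with an estimated correlation in camera and 32 with fry, which tests each list by itself.

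Replicate numbers did not pair the arrays: the 6 correlations of same-numbered deviations ran from -0.064 to 0.033. With the replicate block the counts were 5295, 2491, 992, 2919, 4608 and 651 in the order above, and 22 list calls.

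Of 354 gene values taken through the alternatives, 254 kept direction and call under every alternative in which they were tested, 100 lost their call in at least 1, and 1 changed sign: LHCB4.1 in wild type against uninduced, at 0.108 with quantile normalization. Outside this set, PSAE-1 changed sign with quantile normalization in 4 h and in wild type against uninduced, and the ribosomal genes AT1G52300 and AT2G34480 in 4 h against uninduced. The cause was not tested. The 21 called lists kept their direction in every alternative in which they were tested. The seed genes M10, AT4G36700 and AT1G65090 start near the bottom of the scale and lost their calls against wild type with a pseudocount of 1. Their log2 changes there were 5.62, 5.03 and 3.24, and the reason for the lost calls was not tested.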

Other observations

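The tests of the fluidics run, of the arrays' value distributions and of fusion activity without dexamethasone reported in this part were chosen only after the result had been seen. Some cell wall genes moved, while their list was called neither at 1 h nor at 4 h. Among 20 expansin and XTH genes 7 rose and 1 fell at 1 h, 8 and 2 over the list alone (adjusted p = 0.0916), and 5 rose and 2 fell at 4 h against uninduced (adjusted p = 0.244). XTH18, a xyloglucan-modifying enzyme, rose from 737 ± 74.95 to 4230 ± 819 (SD, n = 2) at 1 h and was at 1209 ± 162 at 4 h, and EXLA1 rose by 1.47 at 1 h and fell by 1.39 from 1 h to 4 h. XTH33 (2.01) and EXPA4 (1.13) were higher at 4 h than in wild type, and XTH20 was lower (-1.51), for 2 up and 1 down of 20, 5 and 4 over the list alone (adjusted p = 0.342). The calcium sensor CML38 rose by 2.00 at 1 h and fell by 1.66 from 1 h to 4 h; of 5 tested CML genes 2 rose at 1 h (adjusted p = 0.229) and 0 were called against wild type (adjusted p = 0.657). The zinc finger gene STZ, the tested member of the touch and wounding list, rose by 3.05 at 1 h, 2.51 at 4 h and 2.28 in wild type. GI, of the circadian clock, rose by 1.22 at 4 h and 1.13 in wild type.

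Single lipid and root genes differed between the line and wild type. AT3G02630, a stearoyl-ACP desaturase, went from 1190 ± 58.8 in wild type and 788 ± 148 in the uninduced line to 2720 ± 83.9 at 4 h, while FATB fell by 0.73 against uninduced and was not called against wild type (-0.44, adjusted p = 0.119); of 3 fatty acid genes 1 rose against wild type, and the list's median (-0.07) and mean (0.22) differed in sign (adjusted p = 0.468). The peroxidase AT3G01190 rose by 1.78 against wild type and AT5G17820 by 0.82, the latter not without 4 h replicate 2 (adjusted p = 0.12) or without wild type replicate 1 (adjusted p = 0.12). Of 7 root-enriched genes 2 rose and 1 fell there (adjusted p = 0.186), and of 3 root markers 1 fell (adjusted p = 0.424), PYK10 by 0.57, a call lost without 4 h replicate 2 (adjusted p = 0.111) or wild type replicate 1 (0.107) or 2 (0.05). Chosen after their values were seen, the transcription factor genes HYH and PHV rose by 2.30 and 1.62 and ULT1, a regulator of meristem size, by 2.55 against wild type. NAI2 fell by 1.23 and JAL34 by 0.83.

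Other lists were not called between the line and wild type. Of 3 transcription factors of embryo and seed maturation 1 rose, the bZIP gene EEL (adjusted p of the list 0.247), and it lost its call without any of the 4 arrays (adjusted p = 0.14 to 0.202). Of 27 UGT genes 1 rose and 3 fell (adjusted p = 0.247), of 10 GST genes 0 were called (0.321), as were 0 of 4 mitochondrially encoded subunits (0.424) and 0 of 4 reference genes (0.785, with a median of 0.03 and a mean of -0.03). In that comparison limma called 2569 probe sets at an unadjusted p under 0.05. Lists with fewer than 3 tested genes were not tested as lists: heat shock had AT1G53540, pathogen defence PDF1.2 (-0.53 against wild type, not called) and the flavonoid pathway DFR (0.48, not called). Repressors of the embryonic programme, gibberellin metabolism and cell division had no gene with a probe set of its own. Among the lists given here, mean and median also differed in sign, with no such list called, at 1 h for the transcription factors, GST, other seed maturation and root-enriched genes, from 1 h to 4 h for the transcription factors and UGT genes, and in wild type for auxin biosynthesis and other seed maturation genes.

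Wild type at 4 h and the uninduced line differed at 4679 probe sets although both lie in the same inferred fluidics run, so the run does not account for them. A difference between the arrays' value distributions is not the whole cause, since 95.4% of the calls were kept in the same direction with quantile normalization, though it stays open for photosystem genes, 4 of 8 of which fell there. A candidate explanation is a higher carbon supply in the treated seedlings at harvest. A list of sugar starvation genes was written after the leading decreases were seen and left out the genes which prompted it. Its choice after the fact limits its independence from these data. Of its 30 members 6 were tested. At 1 h against uninduced 5 of the 6 fell, with a median of -0.96, and 4 fell from 1 h to 4 h. Between the line and wild type the median was -0.09. In wild type against uninduced all 6 fell, with a median of -2.04 (camera p = 1.7e-08, and p = 0.0044 with an estimated correlation). The list's IVD and MCCB share leucine breakdown with MCCA, which prompted it, the other members being AKINBETA1 (-3.34), AT3G15450 (-2.74), AT5G57655 (-2.07) and ATL8 (-0.84, lost without uninduced replicate 2 at adjusted p = 0.324 and either wild type array at 0.0632 and 0.297), and dexamethasone, time of harvest and handling stay open as its origin.

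Among the 355 probe sets higher at 4 h against both controls, 38 were lower in wild type than in the uninduced line. OLEO3 (-1.18) and AT1G04660 (-4.00) were among them. Simulations with both groups equal gave at most 1 such probe set, although a mean of 1559 probe sets were higher against both controls in them. They address only chance values of the shared arrays, since they held no difference between these groups. Over all 15026 tested probe sets 2148 were called lower in wild type, a larger share than 38 of 355. Of the 2148, 1676 were also called lower at 4 h against uninduced, so they could not be among the 355. The shares are therefore not comparable. Fusion activity without dexamethasone could raise probe sets like the 38 in the uninduced line. Of the 355, a further 71 were higher in wild type, a ratio of 0.535 lower per higher. This ratio decides nothing, because wild type also had dexamethasone and 4 h of time. The design leaves line, time and dexamethasone together in this comparison, so the hypothesis stays open.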
